A study of Pseudomonas putida with 3 samples.

How the data were processed

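The series holds 3 RNA-seq libraries of Pseudomonas putida KT2442, a rifampicin-resistant derivative of the soil bacterium KT2440. One library came from a strain with an in-frame deletion of fleQ, per the labels, and the other libraries from the wild type. Per the labels' protocols, cells were grown in LB medium, protected with an RNA-stabilising buffer and spun down. Total RNA was column-purified, treated with DNase I, depleted of ribosomal RNA with magnetic beads, fragmented, copied to cDNA and sequenced on an Illumina HiSeq. The design text says that cultures were pooled before RNA extraction, so each of the 3 libraries stands for a pool and no spread between cultures can be had. The growth protocol describes growth to an optical density (OD600) of about 1.3 and is the same for all libraries, while the labels give OD600 3.5 for 1 wild-type library. CASAVA 1.4 is named in the submitters' processing notes. The aligner, the genome build, the gene annotation and whether counting used the strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be parted, and reads of near-identical copies may have been split.

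Each deposited table lists locus tags with an RPKM value, reads normalised to gene length and to the size of the library, which the authors made. No read counts were used from the tables, but they could be recovered from the RPKM values. The rows are in falling order of read number, and a total and a coding length per locus were sought that turn every value into a whole read number. All 15621 values came out whole within 1e-06 of a read (100%), with 0 breaks of the falling order, and the recovered reads summed to the library totals with a difference of 0. Lengths were required to be multiples of 3, so that property does not show that they are coding lengths. Runs of them did match lengths of coding genes in another strain, as described below. The falling order and nearly complete sums also guided the search. Where the length of a locus listed in a single library was open, it could be doubled if that alone filled a remaining gap. The totals were 9318929 reads for the library labelled fleQ mutant, 6519214 for wild type at OD600 1.3 and 17741981 for wild type at OD600 3.5. The RPKM values are therefore scaled to reads on listed genes. The tables listed 5205, 5208 and 5208 loci and 5229 in at least 1 of them. A locus missing from a table was taken as 0 reads there.

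The tables pair no locus tag with a name, and no annotation of KT2440 or KT2442 was used here. Names were taken from the RefSeq gene table of another strain, NBRC 14164 (assembly ASM41267v1), by matching runs of coding lengths in gene order. A pair was kept when its own lengths differed by at most 2% and at least 6 of the 10 aligned neighbours (5 on each side) had lengths within 1%. Of the 5229 loci, 3207 were paired, 1082 of them with a gene that has a symbol. No coordinate of that assembly is given. In a simulated rearranged genome 99.0% of the pairs joined the right genes (2391 of 2415), and 3 shuffles of the reference lengths gave 0 pairs. As a further check, symbols known from general knowledge of KT2440 had been written down for 261 loci before any change was computed. Of the 173 of these loci with a matched symbol, 154 had the identical symbol, 17 another symbol or copy of that gene, and 2 (pcaG and pcaH) were swapped. Those remembered symbols were used for nothing else. Names are thus matched, not given by the files.

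Changes were computed as log2 of the ratio of RPKM + 1 between 2 libraries, for loci with at least 10 RPKM in at least 1 of them. The added 1 RPKM understates the change of low genes. At 10 RPKM a gene of 1000 bases had about 65.2 reads in the shallowest library and 177 in the deepest. A locus at least 2-fold apart (absolute log2 of at least 1) was counted as higher or lower. Folds of single genes are ratios of RPKM without the added 1, with exact (Clopper-Pearson) 95% intervals from the recovered reads. Intervals cover counting error only, since reads amplified by PCR are not independent molecules and nothing was repeated. With 1 library per condition no test between conditions was possible and no p-value is given. Both comparisons use the wild-type library at OD600 1.3.

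For 30 gene lists fixed before the data were examined, the median log2 change was set against 10000 random lists of the same size drawn from the same 10 classes of mean expression. Its 95% interval is the binomial interval of a median over members, given for lists of at least 6 members. The interval describes the spread of members, not of cultures. Random lists draw loci singly, and the interval takes members as independent. The type VI K1, cellulose and NADH dehydrogenase I lists are each a single run of consecutive tags. Of the 31 flagellar genes, 29 lie in the run from motD to flgM, and many ribosomal protein genes are neighbours too. Neighbouring loci tended to change together, so percentiles and intervals may overstate how unusual such lists are. A list needs 3 members past the expression minimum. Type VI cluster K1 was listed as a range of tags, trimmed to its outermost loci with a fitting matched symbol. Unnamed loci within that range count as members. The lists for cyclic di-GMP, amino acid transport, phage and transposition rested on product descriptions and could not be formed. Neither could those for type VI clusters K2 and K3, the Pea and Peb polysaccharide clusters and the Lap adhesins, because no matched symbol identified them. The alginate and siderophore lists had 0 members past the minimum. The lists for Gac/Rsm regulation and branched-chain breakdown were formed but are not described. Their medians rested on rsmA (804 bases) and rsmI (885 bases), which have the lengths of rRNA methyltransferase genes and not of small RNA-binding regulators, and on hbdH, for 3-hydroxybutyrate dehydrogenase. This was decided after seeing the data. The other 17 lists are reported.

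Genes are named by a rule also fixed beforehand. It took fleQ and a short set of genes for motility, biofilm and their regulation, the 8 named genes with the largest positive and the 8 with the largest negative change per comparison, and up to 2 members per list and direction. Among the fixed genes, fliC, fleS, fleR, cheA, lapA, lapF, bifA, cfcR and hcp had no matched symbol and are not reported by name. Loci named outside the rule are marked as chosen after their values were seen.

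The overlap of both comparisons was set against the number that independent lists would share and against 100 simulated sets of unchanged libraries with counting noise alone. The alternatives tried were 0.1 and 5 RPKM as the added value, no expression minimum or 50 RPKM, centring on the median, rescaling without the top 1% of genes, median-of-ratios size factors on recovered reads, a 4-fold threshold and means in place of medians. Size factors and the rescaling for lists, size factors and other sets of loci past the minimum for the overlap, and lists restricted to loci of identical coding length were chosen after seeing the data. On simulated libraries with known folds, the comparison of the library labelled fleQ mutant called 100% of genes changed 4-fold (50 of 50 higher, 43 of 43 lower). Genes changed exactly 2-fold sit on the threshold, and 32.7% of the higher and 63.4% of the lower ones were called, with 0.124% of unchanged genes. The comparison of densities called 100% of 4-fold genes, 22.9% and 63.4% of 2-fold genes and 0.0249% of unchanged ones. The simulated libraries had counting noise alone, without variation between cultures or preparations. These shares are thus no rates of false calls for the real libraries. Reads were recovered exactly for 99.98% and 99.92% of the simulated genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.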

Results

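FleQ is a transcriptional regulator that, in pseudomonads, drives flagellar genes together with the sigma factor RpoN and also acts on genes for exopolysaccharides. To see which transcripts differ without it, RNA from planktonic Pseudomonas putida KT2442 was sequenced in 3 conditions with 1 library each. By their labels they were a fleQ deletion strain at OD600 1.3, the wild type at OD600 1.3 and the wild type at OD600 3.5. The libraries held 9318929, 6519214 and 17741981 reads on listed genes, with medians of 297, 226 and 584 reads per locus. The chaperonin gene groL took the most reads in both libraries at OD600 1.3, with 1.90% (exact 95% interval 1.89 to 1.91) in the library labelled fleQ mutant and 2.37% (2.35 to 2.38) in the wild type. At OD600 3.5 the first place was held by amaB with 3.39% (3.38 to 3.40). No condition was repeated, so no difference below has a replicate check, and intervals of folds cover counting error only.

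The fleQ locus itself (PP_4373) was read first, since it checks the labels. It had 532 RPKM in the library labelled fleQ mutant (7323 reads), 482 RPKM in the wild type at OD600 1.3 (4642 reads) and 300.03 RPKM in the wild type at OD600 3.5 (7857 reads). The library labelled fleQ mutant was thus not lower at the target but 1.10-fold higher (1.06 to 1.15). The deleted part of the gene is not given in the sources used here, and a value for the whole locus does not show which part was read. The label therefore has no check from its target, and every direction given for this library rests on the label.

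In the library labelled fleQ mutant, flagellar genes were far lower than in the wild type at the same density. Of 31 matched genes for flagellar structure, export, motor and regulation, 30 were at least 2-fold lower and the remaining one was fleQ. The list's median log2 change was -2.83 (95% interval over members -3.41 to -2.31), below the medians of all 10000 random lists, the lowest of which was -0.41. Without fleQ the median over 30 genes was -2.89. The gene fliE, which joins rod and basal body, was 59.3-fold lower (35.7 to 107), at 4.83 against 287 RPKM, and the rod gene flgG 31.4-fold lower (24.4 to 41.0). The hook gene flgE was 14.6-fold lower (12.5 to 17.1), flgK, for a hook-filament junction protein, 15.8-fold (13.7 to 18.4) and the motor gene motD 14.2-fold (11.5 to 17.8). The basal-body gene fliL, the export gene fliO and the switch gene fliM were 27.3-fold (16.2 to 49.3), 22.4-fold (13.0 to 41.6) and 14.8-fold (11.2 to 19.9) lower. These 8 genes were the lowest named genes of the comparison.

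The flagellar sigma factor gene fliA was 3.43-fold lower (3.02 to 3.91), its anti-sigma factor gene flgM 6.25-fold (5.70 to 6.86), and flhF and fleN, which set flagellar placement and number, 2.73-fold (2.53 to 2.94) and 2.62-fold (2.37 to 2.90). The run of 60 loci from motD to flgM had 56 past the expression minimum, of which 47 were at least 2-fold lower, 0 higher and 9 within 2-fold. One unnamed locus of this run, PP_4378, chosen after its values were seen, showed the largest change of any locus in this comparison: 24.5 RPKM against 9511 RPKM, 388-fold lower (354 to 425). Of 3 measured chemotaxis genes, the chemoreceptor gene mcpP was 8.64-fold lower (6.71 to 11.3). The methyltransferase gene cheR, inside the flagellar run, had a log2 change of -0.18 and the receptor gene mcpH one of 0.48.

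**Figure D1:**
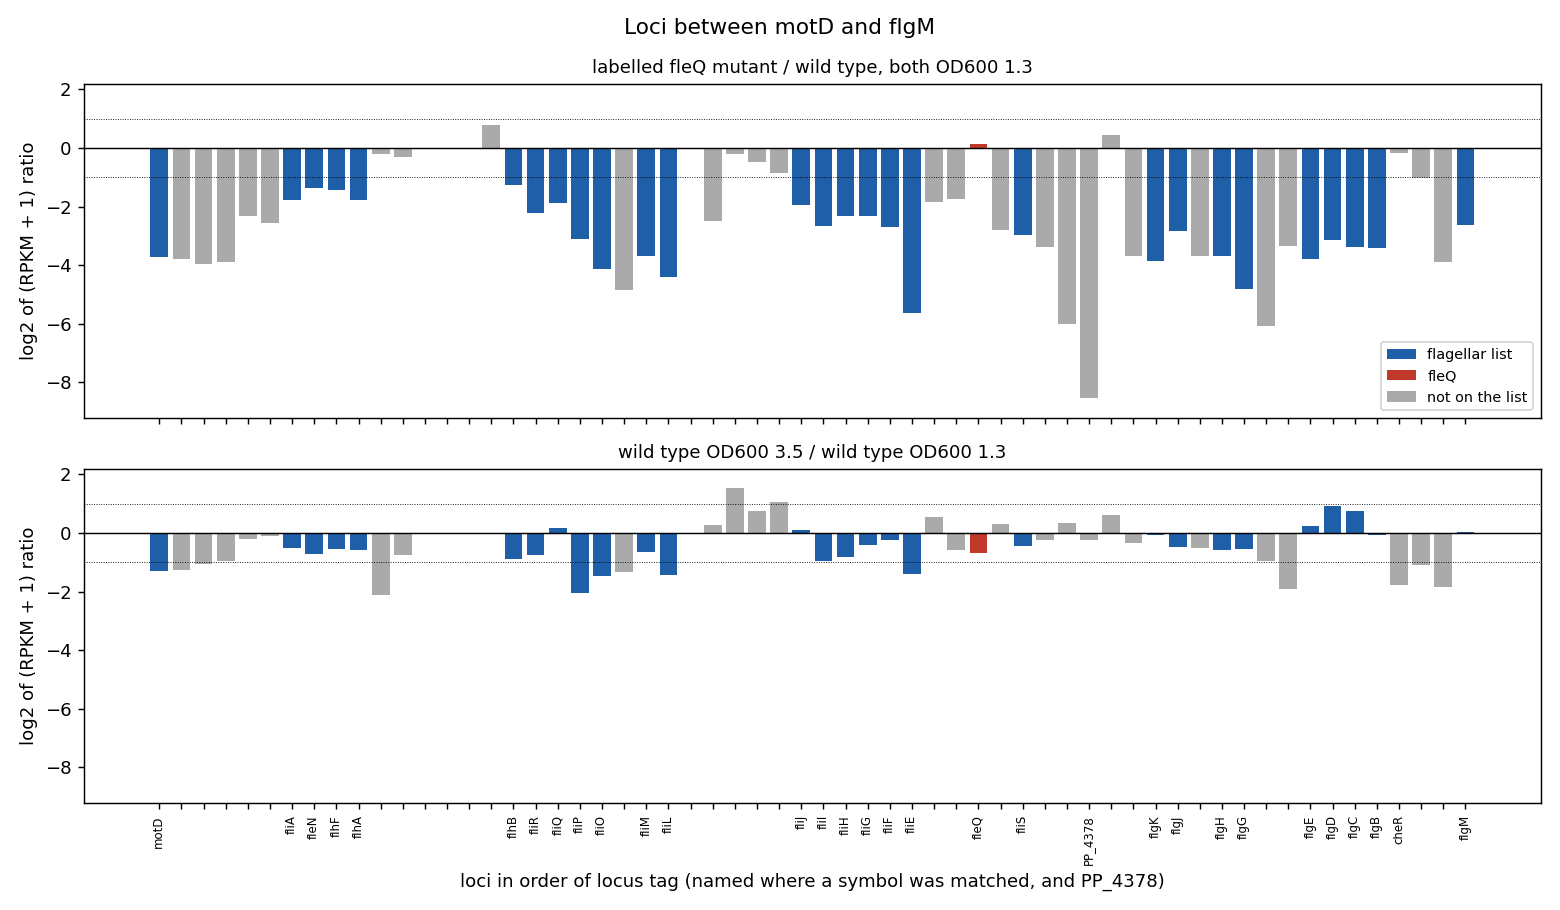
Log2 ratio of RPKM + 1 for the loci from motD to flgM in order of locus tag, in the library labelled fleQ mutant against wild type at OD600 1.3 (top) and in wild type at OD600 3.5 against OD600 1.3 (bottom). Blue bars are genes of the flagellar list, red is fleQ, grey bars are other loci, dotted lines mark 2-fold, and loci under 10 RPKM in both libraries have no bar. In the top panel 47 of 56 loci lie at or below the lower dotted line and fleQ is at 0.14; in the bottom panel 13 of 55 do.

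Genes of type VI secretion, a contact-dependent toxin delivery system, were higher in the library labelled fleQ mutant. All 11 loci of the trimmed list for cluster K1, most with a matched symbol, were at least 2-fold higher. Their median log2 change was 2.09 (1.93 to 2.42), above the medians of all 10000 random lists, whose highest was 0.84. The gene tssA was 5.49-fold higher (4.82 to 6.27), at 201 against 36.7 RPKM, icmH 5.35-fold (4.59 to 6.26), tssK 4.94-fold (4.45 to 5.50), tssG 4.50-fold (3.85 to 5.28) and tssE 4.33-fold (3.67 to 5.12). The second locus of the list, PP_3089, had no matched symbol and was named after its values were seen. It was also by far the most abundant, at 12160 against 1689 RPKM, 7.20-fold higher (7.01 to 7.39).

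Genes of cellulose synthesis were higher in the library labelled fleQ mutant too, at low levels. All 7 matched bcs loci were at least 2-fold higher, with a median log2 change of 1.99 (1.31 to 2.74), above all 10000 random medians, whose highest was 0.72. The cellulase gene bcsZ was 7.03-fold higher (5.84 to 8.53), at 119 against 17.0 RPKM, bcsR 5.13-fold (3.12 to 8.92), bcsB 4.45-fold (3.99 to 4.98) and the synthase gene bcsA 3.70-fold (3.22 to 4.26). The 8 highest named genes of the comparison came from these clusters alone: bcsZ, bcsR, bcsB, tssA, icmH, tssK, tssG and tssE. Among all loci, however, the largest rise was that of the unnamed locus PP_2126, chosen after its values were seen. It stood at 52.7 against 5.35 RPKM (324 against 23 reads), 9.85-fold higher (6.45 to 15.8).

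Other lists differed less between the library labelled fleQ mutant and the wild type. All 52 ribosomal protein genes were within 2-fold, yet all 52 were higher by their counting intervals, with a median of 0.40 (0.32 to 0.46), above all 10000 random medians; rpsA was 1.63-fold higher (1.62 to 1.65) and rplP 1.63-fold (1.60 to 1.65). The 11 NADH dehydrogenase I genes had a median of 0.36, at the 98.2 percentile, with nuoJ 1.45-fold higher (1.34 to 1.57). They are a single run of consecutive tags, and many ribosomal protein genes are neighbours too. The random lists do not allow for this. Chaperone and protease genes had a median of -0.54 (-0.82 to 0.07), at the 0.06 percentile, with 2 of 12 at least 2-fold lower. These were the protease genes hslV, 2.44-fold (2.35 to 2.54), and lon (PP_1443), 2.04-fold (1.97 to 2.11). The other locus matched to lon, PP_2302, was at -0.53. The remaining medians were 0.25 for ATP synthase, 0.21 for housekeeping genes, 0.05 for terminal oxidases, -0.09 for the tricarboxylic acid cycle and glyoxylate shunt, -0.18 for chemotaxis, -0.21 for arginine deiminase, -0.23 for histidine breakdown, -0.24 for pili, -0.27 for sigma factors, -0.29 for stationary phase stress and -0.37 for polyhydroxyalkanoate. Their percentiles ran from 5.76 to 83.4. The value for pili was 0.06 without the expression minimum and -0.06 as a mean, and that for terminal oxidases -0.05 as a mean, so neither had a fixed sign. Other sizes were not fixed either. As means over members, the values were -0.86 for chemotaxis, -0.45 for sigma factors, -0.18 for the tricarboxylic acid cycle list and -0.14 for histidine breakdown. Chemotaxis was at -0.31 without the minimum, stationary phase stress at -0.11 with loci of identical coding length only, and with size factors terminal oxidases were at 0.10 and the tricarboxylic acid cycle list at -0.03. Within these lists, the cytochrome bd oxidase gene cydB was 2.55-fold lower (1.97 to 3.32) and the isocitrate lyase gene aceA 2.13-fold (2.02 to 2.25). The stationary-phase sigma factor gene rpoS was at 379 against 341 RPKM, 1.11-fold higher (1.05 to 1.17).

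Over all loci, 4122 passed the expression minimum. In the library labelled fleQ mutant 88 were at least 2-fold higher and 232 at least 2-fold lower than in the wild type, and 92.2% lay within 2-fold. Counting intervals excluded 1 for 84 of the higher and 231 of the lower loci. Only 24 of the 88 and 50 of the 232 had a matched symbol. The higher count was 56 with an expression minimum of 50 RPKM.

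The wild type at OD600 3.5 was compared with the wild type at OD600 1.3 to see what differs with density. Far more loci differed. Of 4364 loci, 752 were at least 2-fold higher and 897 at least 2-fold lower at OD600 3.5, and 62.2% lay within 2-fold. The counting intervals of all 752 and all 897 excluded 1, and 114 and 276 of them had a matched symbol. The higher count was 495 with a minimum of 50 RPKM. The median log2 change over the 4364 loci was -0.12, so centring on it raises every log2 value below by 0.12. After centring, 852 loci were higher and 774 lower, so the balance of higher and lower loci was not fixed.

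The gene for the stationary-phase sigma factor, rpoS, was 39.1-fold higher at OD600 3.5 (37.5 to 40.7), at 13304 against 341 RPKM. In the stationary phase and stress list 3 of 4 genes were at least 2-fold higher, with a median log2 change of 1.41 at the 96.4 percentile (2.22 as a mean), and hpf, for a ribosome hibernation factor, was 2.71-fold higher (2.66 to 2.76). The largest named increases were amaB, 441-fold (404 to 483), amaA, 204-fold (176 to 239), hglS, 146-fold (131 to 162), and glaH, 113-fold (94.3 to 136). In P. putida amaA, amaB, hglS and glaH are known for lysine breakdown. Next came mmsB, for valine breakdown, 79.5-fold higher (69.0 to 92.1), cydB, 53.7-fold (46.2 to 62.9), and maiA and hppD, for tyrosine breakdown, 45.1-fold (40.9 to 49.8) and 39.5-fold (37.9 to 41.2).

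Ribosomal protein genes were lower at OD600 3.5. Of 52, 41 were at least 2-fold lower, 11 were within 2-fold and 0 higher, with a median log2 change of -1.71 (-1.89 to -1.54), below all 10000 random medians, whose lowest was -1.09. The gene rplJ was 11.5-fold lower (11.2 to 11.8) and rplS 9.05-fold (8.75 to 9.36), while rpmG was at 0.06. Chaperone and protease genes had a median of -2.17 (-3.15 to -1.26), also below all random medians, with 10 of 12 at least 2-fold lower. Among them hslU was 10.5-fold lower (10.1 to 10.9) and lon (PP_1443) 9.29-fold (8.87 to 9.73), while clpP was at 0.15. The other locus matched to lon, PP_2302, was at -0.04. The 11 NADH dehydrogenase I genes had a median of -1.32 (-1.91 to -1.14), at the 0.2 percentile, with 10 at least 2-fold lower, and nuoI was 3.82-fold lower (3.53 to 4.15).

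The lowest named gene at OD600 3.5 was zwf (PP_1022), for an enzyme of sugar breakdown. This glucose-6-phosphate dehydrogenase gene was 32.6-fold lower (30.5 to 34.9). Another locus, PP_5351, also matched the symbol zwf and was not among the 8 lowest named genes. The glyceraldehyde-3-phosphate dehydrogenase gene gap was 13.4-fold lower (12.5 to 14.4) and the Entner-Doudoroff dehydratase gene edd 11.4-fold (10.9 to 11.9). The other genes among the lowest 8 were calA, for an alcohol dehydrogenase, 25.5-fold lower (19.6 to 33.8), the sensor kinase gene aauS, 11.4-fold (9.92 to 13.1), and ssuE, for sulfonate use, 10.97-fold (8.76 to 13.8), besides rplJ and hslU. In the list of the tricarboxylic acid cycle and glyoxylate shunt members went both ways, 3 of 11 higher and 5 lower by at least 2-fold, with a median of -0.90 at the 7.27 percentile (-0.36 as a mean). The isocitrate lyase gene aceA was 6.53-fold higher (6.30 to 6.77) and icd 3.35-fold higher (3.08 to 3.65), while mqo, for malate:quinone oxidoreductase, was 7.25-fold lower (6.85 to 7.67) and sdhC 3.28-fold lower (3.09 to 3.49). The terminal oxidase list had a median of 0.44 (0.29 to 1.02) at the 94.8 percentile and a mean of 1.07, with 5 of 18 at least 2-fold higher. Among these were cydB and ccoG (PP_3543), 7.94-fold (7.15 to 8.85). The other locus matched to ccoG, PP_4259, had a log2 change of 0.42. The list also holds genes for oxidase assembly, such as ccoG.

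Flagellar genes had a median log2 change of -0.57 at OD600 3.5 (-0.81 to -0.41), at the 4.13 percentile, with 7 of 31 at least 2-fold lower and 24 within 2-fold. The export gene fliP was 4.32-fold lower (3.58 to 5.21), the motor gene motB 3.78-fold lower (3.49 to 4.09), flgM was at 0.05 and flgD at 0.93. The fleQ gene was 1.61-fold lower (1.55 to 1.67). All 7 bcs loci were at least 2-fold lower at OD600 3.5, with a median of -1.94 (-2.997 to -1.02), below all random medians, and of -1.28 with 5 RPKM added. The bcsF gene was 11.3-fold lower (4.83 to 30.5) and bcsA 2.19-fold (1.84 to 2.60). All 11 loci listed for type VI cluster K1 were higher by their counting intervals, 6 of them at least 2-fold. Their median was 1.24 (0.75 to 2.38) at the 99.9 percentile. The tssA gene was 5.31-fold higher (4.68 to 6.04) and PP_3089 5.35-fold (5.21 to 5.49).

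The remaining medians at OD600 3.5 were 0.60 for polyhydroxyalkanoate, -0.25 for housekeeping genes, -0.56 for chemotaxis, -0.80 for histidine breakdown, -0.84 for ATP synthase and -0.96 for arginine deiminase, at percentiles from 11.5 to 85.1. The pili median was -0.07, ran from -0.12 to 0.05 over the scalings tried and was 0.21 without the minimum, and the sigma factor median was 0.42 and ran from -0.09 to 0.54, so neither had a fixed sign. Other sizes depended on the setting as well. Without the top 1% of genes the ATP synthase median was -0.49 and that of arginine deiminase -0.61, and the latter was -0.56 with loci of identical coding length only. As means the values were 0.99 for sigma factors, -0.04 for housekeeping genes (median -0.13 after centring), -0.25 for chemotaxis and -1.28 for histidine breakdown. The urocanate hydratase gene hutU was 11.1-fold lower (9.55 to 13.0) and arcD (PP_1003) 4.20-fold lower (3.92 to 4.50). The other locus matched to arcD, PP_1002, had a log2 change of -0.39. The gene atpG was 2.78-fold lower (2.73 to 2.84) and cheR 3.41-fold lower (3.22 to 3.61). The chemoreceptor gene mcpP was 2.99-fold higher (2.71 to 3.32) and, among housekeeping genes, ftsZ 2.13-fold higher (2.08 to 2.17).

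**Figure D2:**
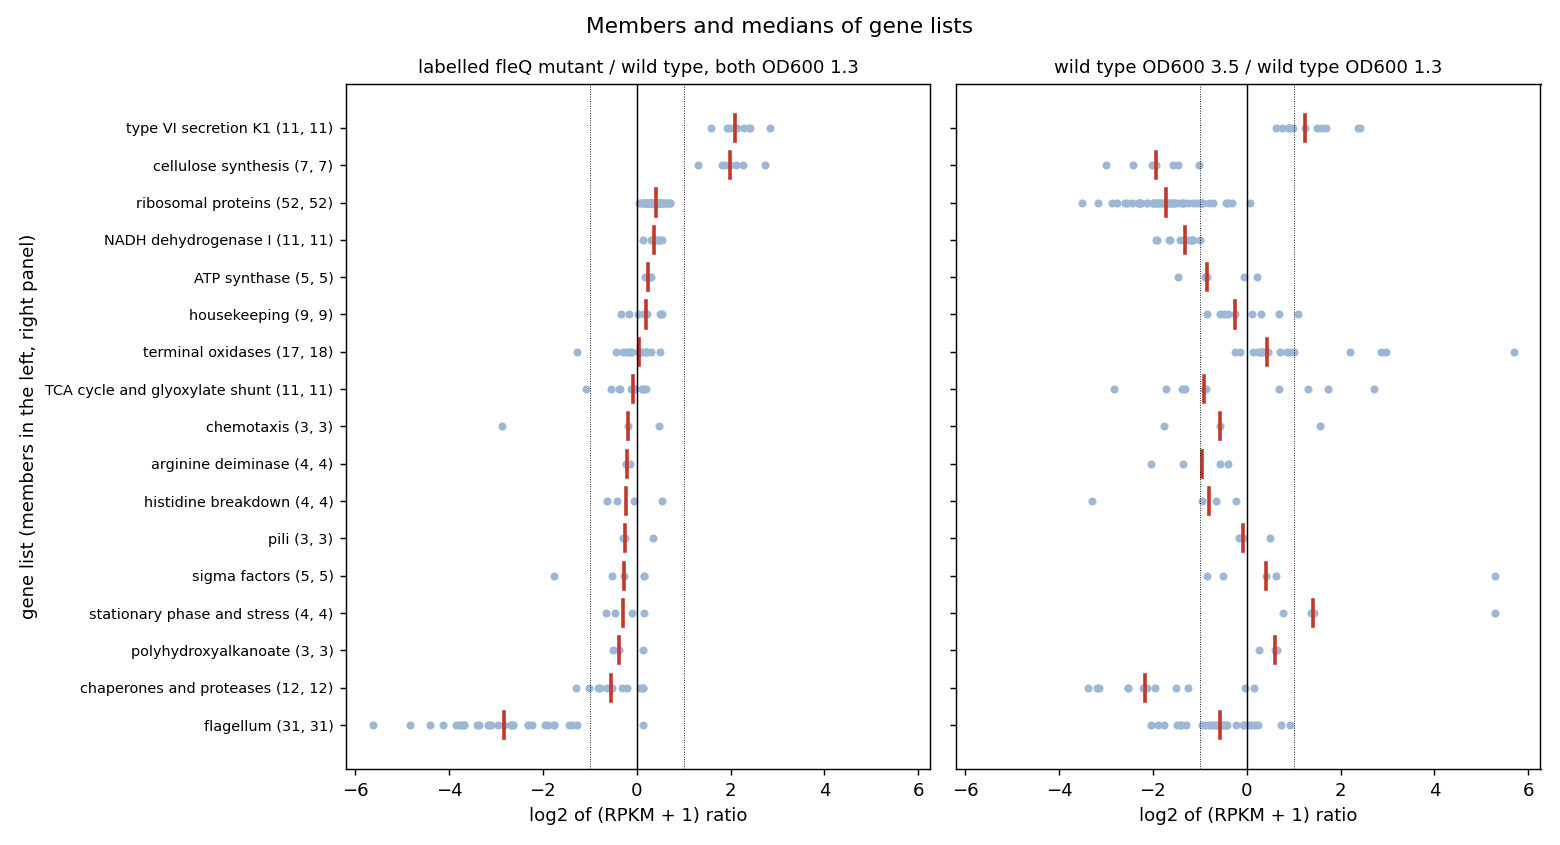
Log2 ratio of RPKM + 1 of each list member (points) and the list median (red line) for the library labelled fleQ mutant against wild type at OD600 1.3 (left) and wild type at OD600 3.5 against OD600 1.3 (right), with the number of members in each panel in brackets. Dotted lines mark 2-fold. The flagellar median is -2.83 on the left and -0.57 on the right, the type VI K1 median 2.09 and 1.24, and the cellulose median 1.99 and -1.94.

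Both comparisons were then set side by side over the 4080 loci past the minimum in each, with directions for the library labelled fleQ mutant resting on its label. These loci included all loci called lower, but only 71 of the 88 and 566 of the 752 called higher, because passing the minimum depends on the change itself. In this library and at OD600 3.5, 22 loci were at least 2-fold higher in both and 78 lower in both. Independent lists would share 9.85 and 51.0 over these loci, or 15.0 and 47.2 with all calls over the 4406 loci past the minimum in any library. With the minimum on the shared wild-type library alone, 13 loci were higher in both, against 8.18. Higher in the first and lower at OD600 3.5 were 20 loci, against 15.6 or 17.9, or 13.5 with the minimum on the shared library. The opposite held for 35, against 32.2 or 39.6, so it lay on no fixed side of chance. The 22 loci included 6 of type VI cluster K1, and the 78 included 7 flagellar genes (motA, motB, motD, fliE, fliL, fliO and fliP). The 20 included every locus from PP_2629 to PP_2638, a run that holds all 7 bcs loci. That run is larger than the excess of the 20 over each expected number given. Several loci in these sets are neighbours in tag order, while the expected numbers take loci as independent. Part of an excess may thus come from single runs of loci. Both comparisons use 1 wild-type library, and part of the excess may come from it, since it cannot be split. Simulated unchanged libraries gave on average 0.45 loci higher in both and 0.23 lower in both, at most 3 of each. The simulation has no variation between cultures, so these numbers do not bound what the shared library adds. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of -0.03 and a covariance of -0.03, where counting noise through the shared library gave 0.68 and 0.01. The covariance left after taking off the simulated one was -0.04. Counting noise is the only variation in the simulation, so its correlation of 0.68 is no reference value for the observed one.

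**Figure D3:**
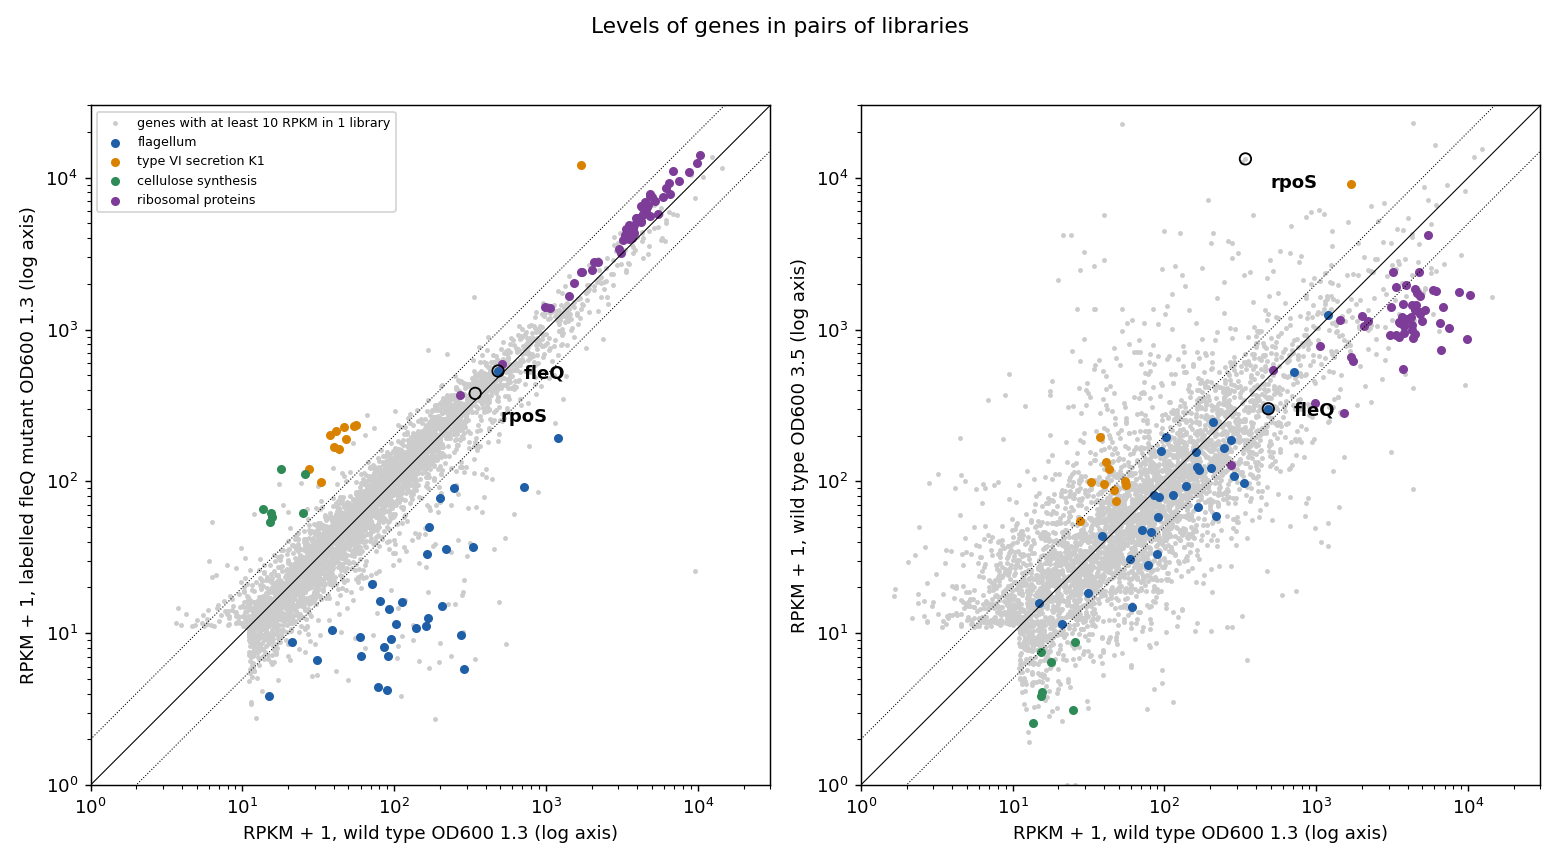
RPKM + 1 of each locus past the expression minimum in the library labelled fleQ mutant (left, y axis) and in wild type at OD600 3.5 (right, y axis) against wild type at OD600 1.3 (x axes), all on log axes. The solid line marks equal levels and dotted lines 2-fold; coloured points are 4 gene lists, and circles mark fleQ and rpoS. On the left 92.2% of loci lie within 2-fold and fleQ lies near the line of equal levels; on the right 62.2% lie within 2-fold and rpoS stands at 13304 against 341 RPKM.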

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

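Single libraries allow no test, so a value is called kept by a rule of range. A list of at least 6 members had to stay within its interval, a smaller list between its lowest and highest member, and a count within 1.5 times. The rule for small lists is loose and does not ask for a fixed sign. Size factors for lists and for the overlap, other minimums for the overlap, lists of identical coding length and the rescaling of lists were chosen after seeing the data. No paired analysis was possible because each condition had 1 library, and no library could be left out. Of 28 counts of higher and lower loci under the alternatives, 26 stayed within 1.5 times. The exceptions had a minimum of 50 RPKM, with 56 loci higher in the library labelled fleQ mutant and 495 higher at OD600 3.5; fewer loci enter at that minimum. All 56 and all 495 were among the loci of the main counts. Of 300 list values, which include 2 lists not described, 296 were kept and 0 changed sign where the median was at least 1 in size. The ribosomal median in the library labelled fleQ mutant was 0.46 with size factors. At OD600 3.5 the polyhydroxyalkanoate value was 0.72 after centring and 0.67 with size factors, and the terminal oxidase value was 1.07 as a mean, with its highest member, cydB, at 5.69. With a 4-fold threshold the overlaps of both comparisons were 2 loci higher in both, 7 lower in both, 2 higher in the library labelled fleQ mutant and lower at OD600 3.5, and 0 the other way; fewer loci pass that threshold. With the minimum set on the shared library alone, 13 loci were higher in both. Of 435 values of named genes, 62 moved by more than their counting interval and 0 changed sign among genes at least 2-fold apart. The bcsR gene, with 6 reads at OD600 3.5 and 18 at OD600 1.3, had an interval of 3.10 to 25.1 for its 8.16-fold lower level. The causes of the other differences were not tested.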

Other observations

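Several further genes with large differences at OD600 3.5 were picked after their values were seen and are given as values. Besides the tyrosine breakdown genes maiA and hppD, the log2 change was 5.20 for fahA and 3.90 for hmgA, which act in the same route. Beside glaH, it was 4.68 for lhgO and 5.12 for the transporter gene gabP. The phenylacetate breakdown genes paaI, paaY, paaG and paaZ stood at 3.86, 3.13, 2.97 and 2.57. The cold-shock family gene cspD stood at 3.59. Propionate genes prpC, acnD and prpF stood at 2.78, 2.72 and 2.74. On the lower side the translation factor gene infA was at -3.06, the chaperonin gene groL at -3.15 and the nucleoid protein gene mvaT at -2.77.

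In the library labelled fleQ mutant, some named genes outside the flagellar, type VI and cellulose clusters stood out after their values were seen. The ribosome rescue gene arfA was at 1.95, ydiJ at 1.73, oscA at 1.62 and ssuE at 1.51. On the lower side fdhA was at -1.69, choW at -1.66, glcF at -1.46 and gbcA at -1.45. Loci next to each other in tag order tended to differ together. In this library 127 pairs of consecutive tags were both at least 2-fold higher or both at least 2-fold lower, against a mean of 12.9 and at most 25 in 1000 permutations of the order. With density it was 668 pairs, against a mean of 281 and at most 328. The random lists did not allow for this, so lists made of neighbours may look more unusual than they are.

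All tests of explanations in the paragraphs below were chosen after the results were seen, and each explanation is a hypothesis. The fleQ locus was not lower in the library labelled fleQ mutant than in the wild type, with an RPKM ratio of 1.10. If the library had come from the wild type at the same density, the flagellar genes other than fleQ would lie near 0, but their median log2 change was -2.89 (-3.41 to -2.32), so the tables argue against that mix-up. Parts of the locus left in place by the deletion may account for reads there. Read only as densely as in the wild type, such parts would give no more than the wild-type RPKM. They could give the ratio of 1.10 only if read more densely. This cannot be told apart from other sources because positions of reads within the locus are not given. A strain changed in some other way stays open, as does a difference in transcription of the locus in the mutant, which was not tested.

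The 11 loci listed for type VI cluster K1 were higher in both comparisons, and both use the wild-type library at OD600 1.3. That library may by chance have been low for these genes, which alone could give both differences. Set against each other without it, the library labelled fleQ mutant and the wild type at OD600 3.5 differed by a median log2 of 0.83, with 10 of 11 loci higher in the former. With 1 library per condition this value does not decide, so a low shared library cannot be told apart from effects of genotype and of density, which remain open.

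A run of 57 consecutive locus tags, PP_4028 to PP_4084, had 0 reads in all 3 libraries together, while the next longest such run was 8 tags. Ordinary low expression is argued against by the reads elsewhere: the lowest of 5251 other windows of 57 tags held 9725 reads. Rows with reads taken out of the tables after the RPKM values had been made are argued against too, since the listed loci fell short of the library totals by 0 reads. In each library the recovery could have filled only a gap equal to the reads of a single locus listed there alone. Loci missing from the annotation, or reads discarded before the RPKM values were made, may account for the 57 tags. This cannot be told apart from loss of the region in the strains, because neither the reads nor the annotation used were analysed here, and no biological explanation was tested.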
